A study of Homo sapiens and Mus musculus with 14 samples.

How the data were processed

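Total RNA was sequenced from cultured cells in 14 libraries: 9 of the human liver cancer line HepG2 and 5 of mouse cells. The HepG2 libraries fell into 4 groups by their labels, with 3 libraries of HepG2 and 2 each of HepG2 with a knockdown of HNF1A, MTF1 or NRF1. The mouse libraries were 3 of the embryonic stem cell line E14TG2a (mESC) and 2 of neural precursor cells derived from that line (mNPC). The labels call the libraries of a group biological replicates without naming separate cultures, so p values measure the spread between these libraries. They do not say how the knockdowns were made or whether the HepG2 libraries received a control treatment; the deposited table heads their columns NT1_r1, NT2_r1 and NT1_r2, and these names are used here. For every group RNA came from cell lysates extracted with a column kit and libraries were made with an Illumina stranded RNA kit, per the labels' protocols.

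The values are raw read counts per gene, as deposited by the authors in 3 tables, 1 each for HepG2, mESC and mNPC. Reads of mNPC were processed with fastp 0.12.2 and STAR 2.5.4a on the mouse genome mm10, per the submitters' processing notes. For HepG2 and mESC the same notes name STAR 2.5.4a and the builds GRCh38 (hg38) and GRCm38 (mm10), and do not name fastp. The tool that counted reads, its strand setting and the annotation release are not given in the sources used here. Without the strand setting, reads of a gene and of a gene on the other strand at the same place cannot be told apart. Of the 94 human genes named by rule in the knockdown comparisons, 44 overlap a gene on the other strand and 16 a gene on their own strand in GENCODE v29 (GRCh38). Further genes, such as MT1X and most transcription factors counted as detected, were not checked. Gene positions are printed as the deposited tables give them. All 94 genes named by rule lay at a position that overlaps the same gene ID in GENCODE v29, and 28 had the same start and end. No mouse annotation was used here. Every column of the 3 tables was matched to a library or group. The knockdown, mESC and mNPC columns match 1 label each, whereas the 3 HepG2 columns match the group without a replicate number.

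There were 31876 genes listed for HepG2, 26787 for mESC and 20653 for mNPC. The mouse tables share 18920 gene IDs; 7867 genes are listed for mESC only and hold 1.66% of the mESC counts, and 1733 are listed for mNPC only and hold 0.321% of the mNPC counts. Of genes without a count in any library of a group's table, 0 were listed for mNPC and 2280 for mESC. A gene without a row in either table was left out of the main mouse comparison and set to 0 in an alternative chosen after the data were seen. For mESC that setting is doubtful, as its table lists genes without a count and lacks mt-Co2, mt-Co3 and mt-Atp6. Because mESC and mNPC come from separate tables with different notes on read processing, cell type and table cannot be told apart in that comparison. The same holds for any difference in culture medium between the cell types.

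Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, dispersions were estimated robustly and each comparison was made with the quasi-likelihood F test (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 9 HepG2 libraries entered 1 fit with a coefficient per group, and 15133 genes were tested. Each knockdown was compared with HepG2 and with the mean of the other 2 knockdowns. The 5 mouse libraries entered a second fit, in which 14183 genes were tested. Log2 fold changes are given with a standard error (SE), taken as the absolute log2 fold change over the square root of the F statistic. This is not the error of a fitted coefficient, and for genes near 0 in 1 group it can be smaller than counting error. CPM are counts scaled to a common library total with TMM factors unless stated, as mean and SD over the libraries of a group. A gene at 0 in every library of a group was set against a floor of 3 counts over that group, which gives 0.0706 CPM for mESC and 0.11 CPM for mNPC. Genes with 1 to 3 counts over a group are given as a ratio with an exact 95% Poisson interval. Floors and intervals cover counting error only.

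Before the data were examined, 56 gene lists were fixed, 37 for the human and 42 for the mouse comparisons, some for both. Symbols were matched without regard to case. A list was tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, 2-sided and adjusted over the lists of 1 comparison, and its members were counted by the gene test, both over all genes and adjusted over the list alone. With a correlation estimated from the data, none of the lists passed in the 4 main comparisons, and 2 lists passed in each of the HNF1A and MTF1 knockdowns against the other 2 knockdowns. That estimate comes from the few libraries of each fit, and it was run neither with a replicate block nor on simulated lists. How often it misses a changed list is not known, so a list that failed it is not shown to be unchanged. The genes named in the text were also fixed by rule. They are the targeted genes and NFE2L1, which has carried the name NRF1 in older literature; the 6 highest and 6 lowest log2 fold changes among genes past the threshold with at least 10 CPM in 1 group, a symbol that is not a clone name and no overlap between the groups' CPM; and the 3 members with the smallest p of each list described. The lists described were those of the knocked down factor and the 6 other lists with the smallest p, or 10 in the mouse comparison. Transcription factors are also named by their detection or level. MT1X and a few further genes of the closing section were chosen after their values were seen.

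Replicates were compared before use. A chi-square of the counts of each pair of libraries of a group, over genes with at least 20 counts in the pair, ranged from 7.97 per degree of freedom (mESC replicates 2 and 3) to 103 (HNF1A knockdown), so every pair differed by more than sampling noise. The column names of the HepG2 table end in r1 or r2. Differences between the r1 and r2 libraries of a group correlated across genes between groups. Over the 6 pairs of groups r lay from 0.378 to 0.589. Genes are not independent replicates, and this correlation carries no p. Libraries with the same ending thus deviate together, as libraries of a batch do. The main fit, its list tests and the fits with 1 library left out carry no term for the ending. A block by the labels' replicate numbers had been planned, but the HepG2 columns carry none, so a fit with the ending as a replicate block was added after the data were seen, and its counts are printed beside the main ones. Between mESC and mNPC the same correlation was 0.00682, so the replicate numbers were not taken to pair these libraries.

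Overlaps of calls between knockdowns were set beside 20 simulated sets in which all 4 groups were drawn from the HepG2 means, beside 20 sets with the r1 and r2 difference of the HepG2 libraries and the dispersion of the fit with the block, and beside the overlap of independent lists. Alternatives were run for the scaling (RLE, upper quartile for mouse, TMM without mitochondrial and the top 20 genes), the low-count filter (none, or at least 5 CPM), DESeq2 1.42.0, a minimum change of 2-fold, the mouse fit without genes at 0 in every library of a table, fits of the 2 compared groups alone, the block and leaving out each library in turn. Detection of transcription factors was counted at 1 CPM over each table's own total, without a test, with 0.5 and 5 CPM as alternatives. The functions were tested on simulated counts drawn from the means and library sizes of these data with 200 genes changed. Of genes changed 4-fold, 75.8% were recovered in the simulated HNF1A and MTF1 comparisons with HepG2 and 78.8% in the NRF1 comparison (15031, 15027 and 15038 genes run), and of those changed 2-fold 26.9%, 19.4% and 34.3%. For mNPC against mESC (14027 genes run) 89.4% and 77.6% were recovered. Against the other 2 knockdowns, the shares of 4-fold changes recovered were 84.8% (HNF1A, 15057 genes run), 78.8% (MTF1, 15053) and 74.2% (NRF1, 15050). Unchanged genes made up 6 of 75, 2 of 65 and 8 of 83 calls in the simulated comparisons of HNF1A, MTF1 and NRF1 knockdown with HepG2. They made up 10 of 94, 2 of 80 and 4 of 76 calls against the other 2 knockdowns and 15 of 158 in the mouse comparison. The 10 of 94 calls (10.6%) exceeded a bound of 10% first set for each comparison, and after that result was seen the bound was applied to all 7 comparisons together. A planted list of 20 genes passed in each simulated comparison and none of the other 19 lists did. Genes were drawn independently of each other in these sets. They therefore do not test the preset correlation, or how often a list passes falsely where its genes move together.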

Results

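Expression was profiled in the cell types used to build and test transcription factor reporters, and in HepG2 cells with knockdowns of 3 factors. HepG2 is a human liver cancer line, E14TG2a is a mouse embryonic stem cell (mESC) line whose columns carry the name 2i_LIF, and the neural precursor cells (mNPC) were derived from E14TG2a. The knockdowns targeted HNF1A, a homeodomain activator of liver genes, MTF1, the metal-responsive activator of metallothionein genes, and NRF1, an activator of mitochondrial and housekeeping genes. Total counts per library ranged from 10894238 to 24695922 in HepG2 cells, from 13877544 to 16402610 in mESC and from 11915188 to 12920967 in mNPC. The HepG2 library NT2_r1 was the shallowest of the HepG2 set and the second MTF1 knockdown library the deepest. Below, log2 fold changes are given ± SE for 2 knockdown against 3 HepG2 libraries, or 2 mNPC against 3 mESC libraries, and CPM as mean ± SD over those libraries. Adjusted p values are from edgeR's quasi-likelihood test for genes and from camera for lists, with Benjamini-Hochberg adjustment.

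Each knockdown lowered its target in both of its libraries. HNF1A (ENSG00000135100, chromosome 12, 120978543 to 121002512, GRCh38) fell from 83.9 ± 2.99 CPM in HepG2 to 20.2 ± 9.69 CPM in the HNF1A knockdown, with a log2 fold change of -2.05 ± 0.26 and an adjusted p of 0.00228. The fall was larger in r1 (-2.67) than in r2 (-1.57). MTF1 (chromosome 1, 37809574 to 37859592) fell from 27.9 ± 4.20 to 7.72 ± 0.350 CPM in the MTF1 knockdown, a log2 change of -1.85 ± 0.27 with an adjusted p of 0.00341. NRF1 (chromosome 7, 129611720 to 129757082) fell from 13.6 ± 2.58 to 4.5 ± 0.641 CPM in the NRF1 knockdown, a log2 change of -1.60 ± 0.27 with an adjusted p of 0.0173 by edgeR's quasi-likelihood test. That call missed the threshold when either NRF1 knockdown library was left out (adjusted p 0.121 and 0.217) and without HepG2 library NT1_r1 (0.0795) or NT2_r1 (0.0583), with log2 changes from -1.41 to -1.76. NFE2L1, another factor once called NRF1, was at 302 ± 10.5 CPM in HepG2 and 295 ± 0.935 CPM in the NRF1 knockdown, with a log2 fold change of -0.03 ± 0.16 and an adjusted p of 0.943. In the MTF1 knockdown NFE2L1 fell to 168 ± 13.7 CPM (-0.85 ± 0.16, adjusted p 0.0105); with either MTF1 knockdown library left out the adjusted p was 0.0934 and 0.0574. None of the 3 targeted genes passed the test in a knockdown of another factor against HepG2.

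**Figure D1:**
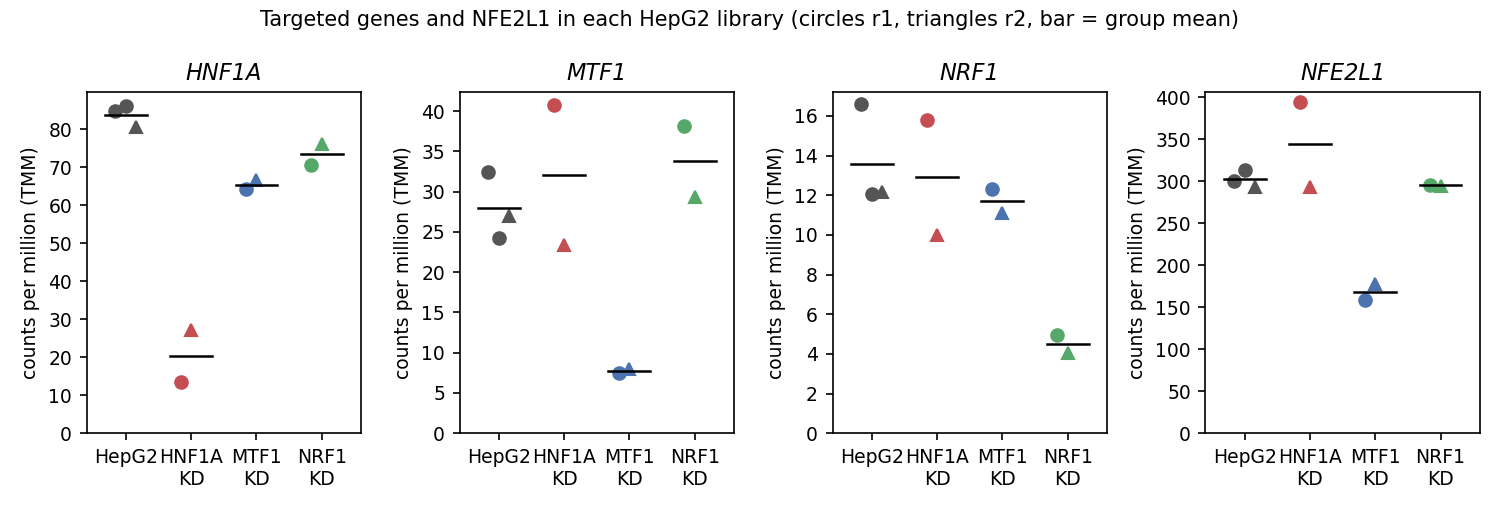
CPM (TMM-scaled, linear axis) of HNF1A, MTF1, NRF1 and NFE2L1 in each of the 9 HepG2 libraries; circles are r1 libraries, triangles r2 libraries and bars group means. Each targeted gene is lowest in both libraries of its own knockdown, and NFE2L1 is lowest in the 2 MTF1 knockdown libraries at a mean of 168 CPM.

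In the HNF1A knockdown some liver genes reported as HNF1A targets and most measured genes of cell division were lower than in HepG2, and most measured p53 targets were higher. Of 34 measured liver genes reported as HNF1A targets, 16 fell and none rose, among them FGB, which encodes the fibrinogen beta chain, from 843 ± 196 to 35.7 ± 10.6 CPM (-4.56 ± 0.28). Of 40 genes of DNA replication and G1/S, 33 fell, and of 35 genes of G2/M and mitosis 26 fell. Of 25 p53 targets 13 rose, among them the cell cycle inhibitor CDKN1A from 133 ± 14.4 to 297 ± 46.1 CPM (1.16 ± 0.17). In all, 1748 of 15133 genes passed the test, 696 higher and 1052 lower.

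Among the reported HNF1A targets, FGA fell by 2.65 ± 0.24 on the log2 scale and GJB1, the connexin of hepatocyte gap junctions, fell by 2.78 ± 0.27, and adjusted over the list alone 20 members were lower. The list passed with an adjusted p of 1.45e-18, and had adjusted p = 0.0879 with an estimated correlation. The 3 fibrinogen chain genes lie side by side on chromosome 4, from FGB at 154563011 to the end of FGG at 154612967, and all 3 fell: FGG went from 521 ± 124 to 120 ± 2.03 CPM (-2.11 ± 0.24). They belong to the acute phase list, where 5 of 12 members fell (5 adjusted over the list alone; adjusted p 1.76e-07, and adjusted p = 0.221 with an estimated correlation) and the median was -1.16 within r1 and 0.03 within r2. They also belong to the coagulation list, where 5 of 24 fell (6 lower and 1 higher adjusted over the list alone; adjusted p 7.24e-06, and adjusted p = 0.228 with an estimated correlation). Of 22 drug metabolism enzymes 10 fell and 1 rose (12 and 2 adjusted over the list alone), with an adjusted p of 4.08e-06 and adjusted p = 0.101 with an estimated correlation. UGT2A3, a glucuronosyltransferase, fell from 145 ± 10.3 to 70.6 ± 8.58 CPM (-1.04 ± 0.15), while UGT1A6 (-3.28 ± 0.43) and UGT2B11 (-4.10 ± 0.53) fell from low levels of 7.71 and 2.38 CPM and share sequence with neighbouring family members, so their counts are uncertain.

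Cell division genes were lower across the cycle in the HNF1A knockdown. CDC45 and MCM2, parts of the replicative helicase, fell by 2.34 ± 0.24 and 1.58 ± 0.17 on the log2 scale, and RFC5, a subunit of the clamp loader, by 1.78 ± 0.19; adjusted over the list alone 38 replication genes were lower and 1 higher (adjusted p 1.99e-38, and adjusted p = 0.178 with an estimated correlation). Mitotic genes followed, with the kinase AURKB at -1.86 ± 0.28, TOP2A at -1.89 ± 0.29 and the checkpoint gene MAD2L1 at -1.73 ± 0.28, and 33 lower adjusted over the list alone (adjusted p 1.22e-22, and adjusted p = 0.228 with an estimated correlation). The fall of the mitotic list differed between the libraries, with a median of -0.99 within r1 and -2.14 within r2. Among p53 targets BTG2, an antiproliferative gene, rose by 2.05 ± 0.23 and TP53I3 by 1.47 ± 0.22 (13 higher adjusted over the list alone; adjusted p 8.55e-09, and adjusted p = 0.221 with an estimated correlation).

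The 6 named genes with the highest log2 fold change in the HNF1A knockdown were LYVE1, a hyaluronan receptor, from 3.39 ± 1.08 to 63.6 ± 11.2 CPM (4.21 ± 0.59), LIF-AS2 (4.11 ± 0.45), the actin-binding LSP1 (3.94 ± 0.36), the arylsulfatase ARSI (3.18 ± 0.49), the glycosyltransferase A4GALT (3.16 ± 0.36) and the lysyl oxidase LOXL2 (3.03 ± 0.41). The 6 with the lowest were PRODH2, a hydroxyproline dehydrogenase (-5.73 ± 0.56), FABP1, the liver fatty acid binding protein (-5.10 ± 0.60), LGALS2 (-5.03 ± 0.41), NPSR1-AS1 (-4.66 ± 0.27), FGB and the diacylglycerol kinase DGKK (-3.96 ± 0.46). Adjusted p of these 12 genes by edgeR's quasi-likelihood test lay between 0.000158 for FGB and 0.00463 for ARSI. LIF-AS2 and NPSR1-AS1 are antisense genes, and their counts may include reads of a gene on the other strand. FABP1 was at 180 ± 123 CPM in HepG2.

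Another 8 lists passed in the HNF1A knockdown. These were NRF2 targets (6 of 23 lower), gluconeogenesis and amino acid catabolism (2 of 16 lower), complement (4 of 18 lower), liver transcription factors (3 of 24 lower), extracellular matrix and mesenchymal genes (4 of 21 higher), glycolysis (5 lower and 1 higher of 16), cytosolic ribosomal proteins (1 of 72 lower) and mitochondrially encoded genes (1 of 13 lower). Adjusted over the list alone the lower counts were 8, 4, 5, 5, 0, 8, 0 and 2 in that order, with 5 higher for matrix genes and 1 for glycolysis. The cytosolic ribosomal median was -0.51 within r1 and 0.11 within r2. Adjusted p of these 8 lists lay from 0.000229 to 0.0363, and with an estimated correlation from adjusted p = 0.182 to 0.822. The other 22 lists did not pass. Proteasome subunits, NF-kB targets, hypoxia genes and blood and endothelial markers had no called member of 31, 12, 19 and 4. Called members numbered 5 of 18 apolipoproteins and lipoprotein assembly genes (4 lower), 5 of 19 zinc transporters (4 lower), 9 of 97 transcription factors with reporters (7 lower), 6 of 11 intestinal and endoderm markers (3 lower), 4 of 24 ATF4 targets (all 4 lower), 3 of 5 metallothioneins (2 higher), 3 of 14 MTF1 targets (2 higher), 3 of 76 oxidative phosphorylation genes (all 3 lower) and 3 of 19 immediate early genes (2 lower). In each of the lists of NRF1 targets (21 measured), mitochondrial ribosomal proteins (73), bile acid genes (16), unfolded protein response (19), heat shock (16) and YAP/TEAD targets (13) 2 genes were called, all lower. The interferon list had 1 higher and 1 lower of 33, cholesterol synthesis 1 lower of 21 and fibroblast markers 1 higher of 3. Adjusted over the list alone, counts differed for apolipoproteins (5 lower), endoderm markers (4 higher), MTF1 targets (2 lower), NRF1 targets (5 lower and 1 higher), transcription factors (1 higher) and YAP/TEAD targets (1 higher), and came to 0 for oxidative phosphorylation, mitochondrial ribosomal proteins and cholesterol synthesis. Median, mean and test differed in sign for the lists of proteasome, interferon, hypoxia, endoderm and fibroblast genes, and the proteasome median of -0.0052 was 0.0069 with RLE scaling.

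With r1 and r2 as a block the HNF1A count was 3802, including all 1748 genes above in the same direction, and a fit of the HNF1A knockdown and HepG2 alone called 1004 genes. With the other 2 knockdowns as controls in place of HepG2, CDC45 (-0.46, adjusted p 0.235 by edgeR's quasi-likelihood test), MCM2 (-0.22, 0.428), RFC5 (-0.27, 0.394), AURKB (-0.32, 0.482) and TP53I3 (0.41, 0.261) did not pass. TOP2A (0.13, 0.808) and MAD2L1 (0.11, 0.841) changed sign and did not pass either. The count was 718 without HepG2 library NT1_r1, 676 without NT2_r1 and 883 without HNF1A knockdown replicate 2.

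In the MTF1 knockdown every measured metallothionein and most cell division genes were lower than in HepG2, and interferon response genes were higher. Metallothioneins are small metal-binding proteins, and all 5 measured fell, with MT2A going from 45.3 ± 6.93 to 4.76 ± 1.04 CPM (-3.26 ± 0.30). All 35 genes of G2/M and mitosis and 37 of 40 of DNA replication fell, with list medians of -2.31 and -1.62. Of 33 interferon response genes 18 rose, among them IFIT3 from 5.81 ± 3.33 to 32.8 ± 1.90 CPM (2.47 ± 0.37). In all, 1911 of 15133 genes passed the test, 804 higher and 1107 lower.

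MT1E (chromosome 16, 56625475 to 56627112, GRCh38) fell from 12.4 ± 1.64 to 0.582 ± 0.0792 CPM (-4.38 ± 0.27), with an adjusted p of 0.000195 by edgeR's quasi-likelihood test. MT1G had 2 counts over the MTF1 knockdown, a level 40.8-fold lower than in HepG2 with an interval of 11 to 342, and MT1X, chosen after its values were seen, had no counts and was at least 12.4-fold lower. Metallothioneins are near-identical in sequence, so how reads were divided among them is uncertain. The list passed with an adjusted p of 1.88e-14 (5 lower adjusted over the list alone), and had adjusted p = 0.157 with an estimated correlation; its median of -4.38 became -4.26 with MT1X at its bound. Of 14 reported MTF1 targets 6 fell, the 5 metallothioneins and the zinc exporter SLC30A1 (-0.99 ± 0.19), and the zinc importer SLC39A10 rose from 33.8 ± 2.26 to 95.7 ± 4.41 CPM (1.5 ± 0.18). That list passed with an adjusted p of 3.68e-05 (7 lower and 1 higher adjusted over the list alone), and had adjusted p = 0.276 with an estimated correlation. Of 19 zinc transporters 3 rose, including SLC39A4 from 81.0 ± 18.4 to 271 ± 67.3 CPM (1.74 ± 0.29), and 1 fell (3 and 2 adjusted over the list alone); the list did not pass (adjusted p 0.568), and its median of -0.07 and its mean of 0.15 differed in sign. The call of SLC30A1 was lost without MTF1 knockdown replicate 1 (adjusted p 0.0888).

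Cell division genes fell in the MTF1 knockdown from replication to mitosis. FEN1, a nuclease of lagging-strand synthesis, fell by 1.74 ± 0.15 on the log2 scale, as did CDC45 (-2.37 ± 0.25) and the sliding clamp PCNA (-1.58 ± 0.17). The kinase AURKA fell from 195 ± 21.2 to 32.6 ± 7.54 CPM (-2.58 ± 0.29), TOP2A to 85.1 ± 27.6 CPM (-2.54 ± 0.30) and the kinesin KIF2C to 14 ± 2.65 CPM (-2.81 ± 0.35). The replication list had an adjusted p of 5.25e-50 (39 lower adjusted over the list alone) and adjusted p = 0.157 with an estimated correlation. The mitosis list had 1.76e-45 (35 lower adjusted over the list alone) and adjusted p = 0.276 with an estimated correlation. Within r1 and r2 the medians over both lists together were -2.15 and -1.82.

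Among interferon response genes, IFIT2 rose by 2.11 ± 0.29 and the RNA sensor IFIH1 from 7.83 ± 0.629 to 20.7 ± 5.63 CPM (1.40 ± 0.21). The list passed with an adjusted p of 8.85e-17 and a median of 1.89 (27 higher adjusted over the list alone), and had adjusted p = 0.276 with an estimated correlation. These genes also moved with the column ending: the list median was 0.85 higher in HepG2 library NT1_r2 than in NT1_r1, and the rise in the MTF1 knockdown was 2.13 within r1 and 1.31 within r2. Of 21 cholesterol synthesis genes 1 rose, PCSK9, from 118 ± 57.4 to 353 ± 53.7 CPM (1.58 ± 0.35; 1 adjusted over the list alone). The list passed with an adjusted p of 8.68e-05 and a median of 0.75, and had adjusted p = 0.701 with an estimated correlation. It too moved with the ending, by 0.96 from NT1_r1 to NT1_r2, and its median was 0.73 within r1 and 0.58 within r2. MSMO1 (1.41 ± 0.42) and MVD (1.45 ± 0.45) did not pass, with adjusted p of 0.0527 and 0.0629 by edgeR's quasi-likelihood test. Both passed with the block (9.60e-05 and 5.92e-05), with DESeq2 (0.00443 and 0.00614) and with the 2 groups alone (0.0305 and 0.048), and MSMO1 with RLE scaling (0.0495). Without NT1_r2 both passed edgeR's quasi-likelihood test as well, at 1.80 and 1.92 (adjusted p 0.0305 and 0.03). PCSK9 was lost without NT1_r1 (0.0625), NT2_r1 (0.0736) or MTF1 knockdown replicate 1 (0.0595) or 2 (0.107).

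Of 73 mitochondrial ribosomal protein genes 10 fell in the MTF1 knockdown (13 adjusted over the list alone), among them MRPL40 (-1.42 ± 0.19), MRPS10 (-1.31 ± 0.18) and MRPL35 (-1.18 ± 0.20). The list had an adjusted p of 1.09e-07 and a median of -0.40, and adjusted p = 0.602 with an estimated correlation. Of 31 proteasome subunit genes 11 fell (14 adjusted over the list alone), with PSMD11 going from 170 ± 6.12 to 105 ± 2.98 CPM (-0.69 ± 0.13), PSMD12 at -0.77 ± 0.15 and PSMD1 at -0.75 ± 0.15. That list had an adjusted p of 1.64e-05 and a median of -0.36, and adjusted p = 0.531 with an estimated correlation. MRPL35 was lost without MTF1 knockdown replicate 2 (adjusted p 0.0609), and PSMD11, PSMD12 and PSMD1 were lost without NT1_r1 (0.055, 0.0595 and 0.0729), MTF1 knockdown replicate 1 (0.0678, 0.0604 and 0.0847) or replicate 2 (0.0871, 0.103 and 0.106); PSMD1 was also lost without NT2_r1 (0.0505).

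The 6 named genes with the highest log2 fold change in the MTF1 knockdown were TUBA1A (4.36 ± 0.37), ACSM3 (4.34 ± 0.43), ERP27 (3.95 ± 0.36), PLA2G3 (3.88 ± 0.90), IFI6 (3.66 ± 0.81) and the cytokine receptor IL21R (3.39 ± 0.63). ACSM3, a medium-chain acyl-CoA synthetase, went from 3.87 ± 0.432 to 78.6 ± 16.2 CPM. TUBA1A shares sequence with other tubulin genes and its level is uncertain. Besides MT1E and MT2A, the lowest were ANLN (-3.24 ± 0.53), the kinesin KIF18A (-2.98 ± 0.51), PBK (-2.87 ± 0.42) and CKAP2L (-2.85 ± 0.55), genes used in mitosis and cytokinesis. PLA2G3 and IFI6 were lost without NT1_r1 (adjusted p 0.0908 and 0.0669) or NT2_r1 (0.0812 and 0.0816). Without MTF1 knockdown replicate 1, IFI6 (0.0722), ANLN (0.0556), KIF18A (0.0623) and CKAP2L (0.0592) were lost, and without replicate 2 PLA2G3 (0.174), IFI6 (0.0633), IL21R (0.0841) and CKAP2L (0.0881). Without a low-count filter PLA2G3 (0.19), IFI6 (0.176) and ANLN (0.0661) were lost.

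Another 10 lists passed in the MTF1 knockdown. Genes rose in coagulation (5 of 24), complement (4 of 18), apolipoproteins and lipoprotein assembly (3 of 18), drug metabolism (3 of 22) and extracellular matrix genes (2 of 21), and fell in glycolysis (5 of 16), heat shock (6 of 16), cytosolic ribosomal proteins (2 of 72) and oxidative phosphorylation (1 of 76), while the unfolded protein response had no called gene of 19. Adjusted over the list alone 7, 7, 5, 3 and 2 were higher in the first 5 lists, and 10, 10, 2 and 1 lower in the next 4, with 1 heat shock gene higher. Their adjusted p lay from 0.000348 to 0.0231, and with an estimated correlation from adjusted p = 0.276 to 0.856. The other 18 lists did not pass, and mitochondrially encoded genes, liver transcription factors, fibroblast markers and blood and endothelial markers had no called member of 13, 24, 3 and 4. Called members were 5 higher and 1 lower of 25 p53 targets, 2 higher and 5 lower of 97 transcription factors with reporters, 1 higher and 2 lower of 34 HNF1A targets and of 23 NRF2 targets, and 2 lower of 21 NRF1 targets. There were 3 higher of 16 gluconeogenesis genes, 2 higher of 12 acute phase genes, 1 higher each of 16 bile acid, 12 NF-kB and 13 YAP/TEAD genes, and 1 higher and 1 lower each of 24 ATF4 targets, 19 hypoxia, 19 immediate early and 11 endoderm genes. Adjusted over the list alone, counts differed for ATF4 targets (2 and 2), immediate early genes (1 lower), endoderm markers (2 higher) and blood markers (1 higher and 1 lower). Median and test differed in sign for bile acid and NF-kB genes, and the NF-kB median of -0.02 became 0.0031 with TMM without mitochondrial and top genes.

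With r1 and r2 as a block the MTF1 count was 3936, including all 1911 genes above in the same direction. With the other 2 knockdowns as controls, CDC45 (-0.51, adjusted p 0.22), PCNA (-0.40, 0.17), TOP2A (-0.84, 0.106), CKAP2L (-1.59, 0.103), KIF18A (-1.84, 0.054), IFI6 (2.74, 0.0505), PSMD11 (-0.32, 0.165) and PSMD12 (-0.26, 0.341) did not pass. The count was 784 without HepG2 library NT1_r1, 881 without NT2_r1, 499 without MTF1 knockdown replicate 1 and 601 without replicate 2.

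In the NRF1 knockdown DNA replication genes and a few mitochondrial genes were lower than in HepG2. Of 40 replication genes 22 fell, among them UNG, which removes uracil from DNA, from 71.8 ± 8.60 to 12 ± 5.34 CPM (-2.58 ± 0.31). Of 21 reported NRF1 targets 2 fell: TFB2M, a mitochondrial transcription factor, from 40.6 ± 4.07 to 20.8 ± 2.48 CPM (-0.96 ± 0.17), and cytochrome c (CYCS) from 210 ± 7.36 to 120 ± 15.8 CPM (-0.81 ± 0.14). In all, 405 of 15133 genes passed the test, 85 higher and 320 lower.

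The NRF1 target list had an adjusted p of 0.00207 and a median of -0.31 (5 lower adjusted over the list alone), and adjusted p = 0.434 with an estimated correlation; TFAM, another member, was at -0.76 ± 0.18 with an adjusted p of 0.0571 by edgeR's quasi-likelihood test. Of 76 nuclear-encoded oxidative phosphorylation genes only CYCS fell (1 adjusted over the list alone; adjusted p 0.0369, and adjusted p = 0.868 with an estimated correlation), with NDUFA12 at -1.05 ± 0.24 and NDUFA8 at -0.94 ± 0.23 above the threshold (0.0516 and 0.063). Of 73 mitochondrial ribosomal protein genes MRPL19 (-1.13 ± 0.16) and MRPL17 (-1.07 ± 0.20) fell (2 adjusted over the list alone; adjusted p 0.0161, and adjusted p = 0.868 with an estimated correlation), and MRPS18B was at -0.70 ± 0.17 (0.0607). The oxidative phosphorylation list was lost without NT2_r1 (0.142), NT1_r2 (0.166) or NRF1 knockdown replicate 2 (0.121), and the mitochondrial ribosomal list without NT2_r1 (0.116) or replicate 2 (0.153). TFB2M and CYCS were lost without NT1_r1 (0.0925 and 0.115), NT2_r1 (0.087 and 0.0832), replicate 1 (0.121 and 0.121) or replicate 2 (0.258 and 0.324). MRPL19 and MRPL17 were lost without NT1_r1 (0.0551 and 0.0519), replicate 1 (0.0932 and 0.172) or replicate 2 (0.153 and 0.222), and MRPL17 also without NT2_r1 (0.106) or NT1_r2 (0.0597). The block added TFAM (adjusted p 0.00544), NDUFA12 (0.011), NDUFA8 (0.0167) and MRPS18B (0.0153), all lower, as did DESeq2 and the fit of the 2 groups alone. With the other 2 knockdowns as controls TFB2M (-0.31, adjusted p 0.305), CYCS (-0.42, 0.119) and MRPL17 (-0.54, 0.141) did not pass.

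Replication genes RFC5 and RFC2, of the clamp loader, fell in the NRF1 knockdown (-1.56 ± 0.19 and -1.24 ± 0.18), and adjusted over the list alone 38 were lower (median -1.02, adjusted p 3.38e-37, and adjusted p = 0.31 with an estimated correlation). Of 35 mitosis genes MAD2L1 (-1.77 ± 0.28) and TOP2A (-1.50 ± 0.29) fell, CDK1 was at -1.31 ± 0.34 (adjusted p 0.0769 by edgeR's quasi-likelihood test), and 23 were lower adjusted over the list alone (median -0.97, adjusted p 1.52e-16, and adjusted p = 0.834 with an estimated correlation). Over both lists the median was -1.02 within r1 and -0.92 within r2. RFC2 was lost without NT1_r1 (0.0508) and RFC5 and RFC2 without NRF1 knockdown replicate 1 (0.0857 and 0.0995) or 2 (0.055 and 0.145). MAD2L1 and TOP2A were lost without NT1_r1 (0.0622 and 0.0858), NT2_r1 (0.0673 and 0.108), replicate 1 (0.103 and 0.187) or replicate 2 (0.171 and 0.181), and TOP2A without NT1_r2 (0.0588). CDK1 passed with the block (0.00431), with DESeq2 (0.0035) and with the 2 groups alone (0.0399). RFC2 (-0.04, adjusted p 0.935 by edgeR's quasi-likelihood test) did not pass with the other 2 knockdowns as controls. RFC5 (0.06, 0.904), MAD2L1 (0.04, 0.955) and TOP2A (0.71, 0.151) changed sign there and did not pass either.

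Of 16 glycolysis genes 3 fell in the NRF1 knockdown (7 adjusted over the list alone): GPI (-0.91 ± 0.15), PKM (-0.74 ± 0.16) and TPI1 (-0.84 ± 0.18), with a list adjusted p of 0.000713 and adjusted p = 0.673 with an estimated correlation. Of 31 proteasome genes PSMD11 (-0.67 ± 0.13) and PSMA4 (-0.78 ± 0.17) fell (4 adjusted over the list alone) and PSMD12 was at -0.66 ± 0.15; the list had an adjusted p of 0.000364 and adjusted p = 0.868 with an estimated correlation. Of 16 heat shock genes 0 passed over all genes and 10 were lower adjusted over the list alone, with HSPH1 at -0.69 ± 0.16, HSP90AA1 at -0.76 ± 0.19 and DNAJA1 at -0.65 ± 0.18 (list adjusted p 3.98e-06, and adjusted p = 0.31 with an estimated correlation). Of 19 unfolded protein response genes 0 passed by either adjustment, with EDEM1 at -0.64 ± 0.19, CRELD2 at -0.54 ± 0.18 and SDF2L1 at -0.65 ± 0.23 (list adjusted p 0.00262, and adjusted p = 0.868 with an estimated correlation, lost without NRF1 knockdown replicate 2 at 0.142). The 5 called genes of this paragraph, GPI, PKM, TPI1, PSMD11 and PSMA4, were lost without NT1_r1 (0.0832, 0.14, 0.107, 0.141 and 0.14), NT2_r1 (0.074, 0.149, 0.145, 0.109 and 0.149), NRF1 knockdown replicate 1 (0.121, 0.213, 0.202, 0.193 and 0.172) or replicate 2 (0.235, 0.378, 0.369, 0.345 and 0.378). PKM, TPI1, PSMD11 and PSMA4 were also lost without NT1_r2 (0.0654, 0.0643, 0.0556 and 0.0677), MTF1 knockdown replicate 1 (0.0632, 0.0738, 0.0547 and 0.0656) or replicate 2 (0.063, 0.0734, 0.0541 and 0.0651). With r1 and r2 as a block PSMD12 (adjusted p 0.00619), HSPH1 (0.0114), HSP90AA1 (0.0132), DNAJA1 (0.00582), EDEM1 (0.0308), CRELD2 (0.0219) and SDF2L1 (0.0266) passed, all lower. PSMD12, HSPH1 and HSP90AA1 also passed with DESeq2 and with the 2 groups alone, and DNAJA1 with DESeq2. With the other 2 knockdowns as controls GPI (-0.17, adjusted p 0.582), PKM (-0.31, 0.296), TPI1 (-0.23, 0.529), PSMD11 (-0.29, 0.219) and PSMA4 (-0.61, 0.0599) did not pass.

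The 6 named genes with the highest log2 fold change in the NRF1 knockdown were ACSM3 (2.80 ± 0.42), the ectonucleotidase NT5E (1.94 ± 0.18), KDM8 (1.90 ± 0.24), the intraflagellar transport gene IFT122 (1.90 ± 0.26), CACFD1 (1.84 ± 0.25) and TMEM143 (1.80 ± 0.22). NT5E went from 31.3 ± 5.37 to 120 ± 5.69 CPM. The 6 with the lowest were PUDP (-2.96 ± 0.22), COCH (-2.70 ± 0.23), the snRNP assembly gene GEMIN2 (-2.68 ± 0.25), UNG, SUMF1 (-2.56 ± 0.29) and ORC1 of the origin recognition complex (-2.52 ± 0.37). PUDP went from 21.3 ± 3.21 to 2.73 ± 0.172 CPM with an adjusted p of 0.000943 by edgeR's quasi-likelihood test. ACSM3 was lost without NT1_r1 (0.0597), NT2_r1 (0.0654) or NRF1 knockdown replicate 2 (0.0741), and ORC1 without replicate 1 (0.0932) or 2 (0.122). KDM8 (0.0775), IFT122 (0.0703), CACFD1 (0.0775), TMEM143 (0.0704) and SUMF1 (0.0538) were lost without replicate 2. ACSM3 (0.38, adjusted p 0.646) and ORC1 (-0.36, 0.623) did not pass with the other 2 knockdowns as controls.

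Another 4 lists passed in the NRF1 knockdown: cytosolic ribosomal proteins, coagulation genes and mitochondrially encoded genes had 0 called of 72, 24 and 13, and p53 targets had 1 higher of 25, with the same counts adjusted over the list alone. Their adjusted p lay from 0.00309 to 0.0335, with adjusted p = 0.868 with an estimated correlation in each. Of the 24 lists that did not pass, 6 had called members: acute phase (1 higher of 12), gluconeogenesis (1 higher of 16), ATF4 targets (1 higher of 24), YAP/TEAD targets (1 higher of 13), bile acid genes (1 lower of 16) and transcription factors with reporters (1 lower of 97). The lists of HNF1A targets, MTF1 targets, metallothioneins, zinc transporters, complement, apolipoproteins, drug metabolism, liver transcription factors, cholesterol synthesis, interferon response, NF-kB, NRF2 targets, hypoxia, immediate early, extracellular matrix, endoderm, fibroblast and blood genes had 0. Adjusted over the list alone, counts differed for zinc transporters (2 higher and 3 lower), drug metabolism (1 lower) and YAP/TEAD targets (2 higher). Median and test differed in sign for fibroblast markers, and median and mean for zinc transporters.

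With r1 and r2 as a block the NRF1 count was 1777, including all 405 genes above in the same direction; DESeq2 called 1110, the fit without a low-count filter 991 and a fit of the NRF1 knockdown and HepG2 alone 778. The count was 77 without NT1_r1, 87 without NT2_r1, 251 without NT1_r2, 31 without NRF1 knockdown replicate 1, 13 without NRF1 knockdown replicate 2, and 863 and 886 without HNF1A knockdown replicate 1 and 2.

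**Figure D2:**
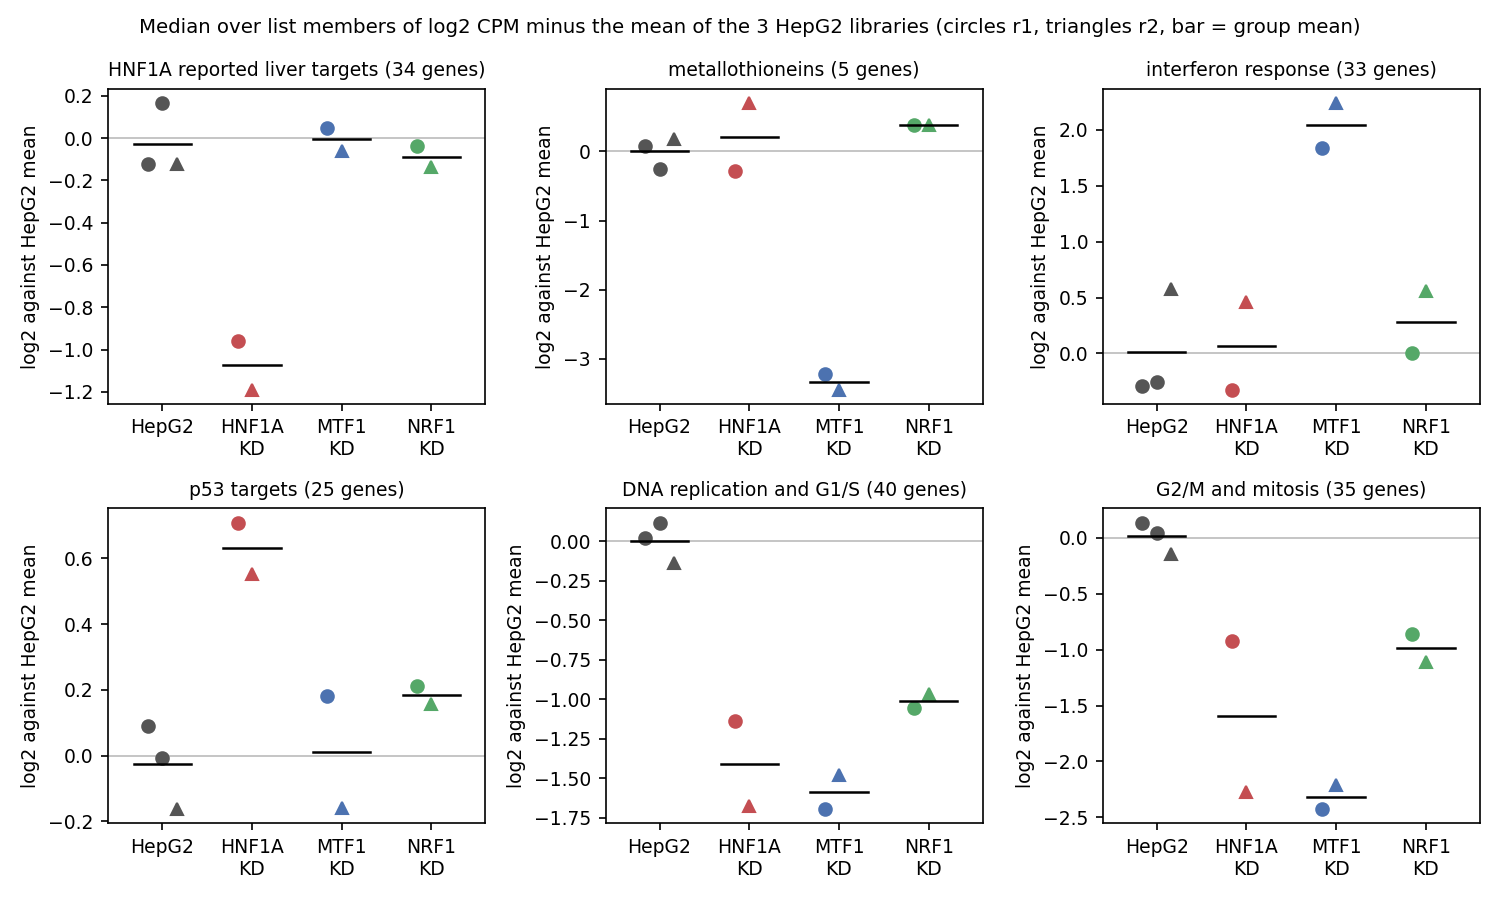
Median log2 CPM of gene lists in each of the 9 HepG2 libraries relative to the mean of the 3 HepG2 libraries without a knockdown. Mitosis genes lie at -2.42 and -2.21 in the MTF1, -0.92 and -2.27 in the HNF1A and -0.86 and -1.11 in the NRF1 knockdown libraries r1 and r2. Interferon genes lie at 1.84 and 2.24 in the MTF1 knockdown libraries and at 0.58 in HepG2 library NT1_r2.

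Each knockdown was also compared with the mean of the other 2 knockdowns, a contrast from which a shift shared by all 3 drops out. HNF1A targets stayed lower in the HNF1A knockdown, with 14 of 34 called (19 adjusted over the list alone) and a median of -0.78. Metallothioneins were lower in the MTF1 knockdown (5 of 5, median -4.97) and interferon genes higher (15 of 33, median 1.82). HNF1A, MTF1 and NRF1 were each lower in their own knockdown, at -1.78 ± 0.25, -2.09 ± 0.27 and -1.45 ± 0.26, with adjusted p of 0.00323, 0.00317 and 0.0159 by edgeR's quasi-likelihood test.

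In the HNF1A knockdown 1435 genes were called against the other 2 knockdowns, 714 higher and 721 lower. The HNF1A target list (adjusted p 2.38e-19) and drug metabolism enzymes (12 lower of 22, 16 lower and 2 higher adjusted over the list alone, 2.84e-10) held with an estimated correlation, each at adjusted p = 0.0333. Coagulation genes (11 lower of 24, 15 adjusted over the list alone) had adjusted p = 0.066 with an estimated correlation. Of 25 p53 targets 10 were higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p 1.90e-05, and adjusted p = 0.266 with an estimated correlation). Replication genes had 2 higher and 2 lower of 40 and mitosis genes 1 higher of 35, and neither list passed (0.694 and 0.477). The count was 3354 with the block, 801 without MTF1 knockdown replicate 2, and 856 and 731 without NRF1 knockdown replicate 1 and 2.

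In the MTF1 knockdown 887 genes were called against the other 2 knockdowns, 486 higher and 401 lower. Metallothioneins (5 lower adjusted over the list alone, adjusted p 4.36e-24) and drug metabolism enzymes (7 higher of 22, 9 adjusted over the list alone, 8.89e-11) held with an estimated correlation, each at adjusted p = 0.0321. The drug metabolism difference includes the fall of these genes in the HNF1A knockdown (median -1.18 against HepG2), and in the MTF1 knockdown against HepG2 their median was 0.48 with 3 called higher. The interferon list (27 higher adjusted over the list alone, 1.07e-23) had adjusted p = 0.125 with an estimated correlation. Of 35 mitosis genes 6 were lower (28 adjusted over the list alone; median -1.05, 1.80e-16, and adjusted p = 0.332 with an estimated correlation), with medians of -1.46 within r1 and -0.52 within r2. Against HepG2 within r2, the mitosis median was -2.07 in the MTF1 knockdown and -2.14 in the HNF1A knockdown. The count was 2736 with the block, 1578 without a low-count filter and 1480 with DESeq2. It was 553 without NT1_r1, 586 without NT2_r1, 198 and 193 without MTF1 knockdown replicate 1 and 2, and 397 and 529 without NRF1 knockdown replicate 1 and 2.

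In the NRF1 knockdown 692 genes were called against the other 2 knockdowns, 351 higher and 341 lower. Of 35 mitosis genes 3 were higher (25 adjusted over the list alone; median 0.95, adjusted p 1.07e-14, and adjusted p = 0.52 with an estimated correlation), and of 40 replication genes 5 were higher and 1 lower (21 and 2 adjusted over the list alone; 6.27e-08, and adjusted p = 0.623 with an estimated correlation). Against HepG2 both lists were lower, so these differences come from larger falls in the other knockdowns. Of 5 metallothioneins 4 were higher (5 adjusted over the list alone; 1.43e-11, and adjusted p = 0.167 with an estimated correlation), which reflects their fall in the MTF1 knockdown, as 0 of 5 were called in the NRF1 knockdown against HepG2 (median 0.38). Of 21 NRF1 targets 1 was higher (1 higher and 1 lower adjusted over the list alone), and the list did not pass (0.342). The count was 2457 with the block, 1326 without a low-count filter and 1379 with DESeq2. It was 358 without NT1_r1, 370 without NT2_r1, 1233 without HNF1A knockdown replicate 1, 267 and 414 without MTF1 knockdown replicate 1 and 2, and 82 and 101 without NRF1 knockdown replicate 1 and 2.

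The knockdowns shared called genes, among them genes of cell division. The HNF1A and MTF1 knockdowns shared 190 genes called higher and 419 called lower, the HNF1A and NRF1 knockdowns 22 and 109, and the MTF1 and NRF1 knockdowns 49 and 146. In all 3 knockdowns 17 genes were higher and 90 lower, and 20 of the 90 belonged to the lists of replication and mitosis. Independent lists of these sizes would share 37.0 and 77.0, 3.91 and 22.2, and 4.52 and 23.4 genes, and 20 simulated sets of unchanged groups against the same controls shared a median of 0 with a maximum of 1. Those sets leave out the r1 and r2 difference, to which the controls (2 r1 and 1 r2) and the knockdowns (1 of each) are exposed unequally. In 20 further sets, chosen after the data were seen, each library was drawn from the HepG2 mean of its own ending, and the median and the maximum were 0 for each pair. No gene is changed in either kind of set, so a shared count near 0 could be foreseen. It cannot show how much sharing the common controls create among groups that do have changes. Calls in opposite directions numbered 17 and 27, 8 and 4, and 6 and 3. Across genes, which are not independent replicates, fold changes correlated at 0.432, 0.375 and 0.538 (simulated medians 0.406, 0.414 and 0.408, or 0.462, 0.466 and 0.46 with the endings), so the correlations of the first 2 pairs did not exceed those of unchanged groups with the endings. Changes found in only 1 knockdown lower a correlation, and unchanged groups have none. The comparison of correlations therefore does not decide whether changes are shared. Covariances were 0.273, 0.179 and 0.251 against simulated medians of 0.0723, 0.0744 and 0.0732, or 0.056, 0.0548 and 0.0554 with the endings. The 3 control libraries cannot be split with 2 in each part, so part of the sharing may come from the shared controls. With the block the shared counts were 1580, 761 and 985.

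Neural precursor cells differed from the stem cells they were derived from in most genes measured. Pluripotency factors were lower in mNPC, with Tfcp2l1 going from 917 ± 111 to 0.22 ± 0.00819 CPM (-11.97 ± 0.23) and Klf4, a factor maintained by LIF, from 361 ± 55.8 to 3.55 ± 0.335 CPM (-6.66 ± 0.19). Most markers of neural progenitors and astrocytes were higher, while of 13 neuron markers 5 were higher and 7 lower. Among the higher genes were Ncan, a brain proteoglycan, going from 0.688 ± 0.0948 to 1060 ± 3.80 CPM (10.58 ± 0.13) and the glial glutamate transporter Slc1a3 from 2.74 ± 0.363 to 1412 ± 87.4 CPM (9.01 ± 0.13). In all, 11652 of 14183 genes passed the test, 5914 higher and 5738 lower in mNPC. Cell type, table and any difference in culture medium cannot be told apart in these differences. The scalings used take most genes as unchanged, whereas most genes were called here. The split into higher and lower, with a median of 0.041 over all genes, rests on that assumption. So do small list medians. Coordinates below are mm10.

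Of 13 naive pluripotency genes 12 fell and 1 rose, with Klf5 at -7.10 ± 0.14 and Klf2 at -6.52 ± 0.14 (adjusted p 1.70e-19, and adjusted p = 0.344 with an estimated correlation). All 7 general pluripotency genes fell, among them Trim71 (-5.82 ± 0.14), Mycn (-7.59 ± 0.23) and the DNA methyltransferase Dnmt3b (-4.89 ± 0.16), with an adjusted p of 2.45e-07 and adjusted p = 0.367 with an estimated correlation. Of 12 LIF and STAT3 response genes 8 fell and 3 rose, with Bcl3 at -8.54 ± 0.26 (adjusted p 0.000143, and adjusted p = 0.367 with an estimated correlation). Of 35 neural progenitor markers 30 rose and 4 fell, with Bcan at 9.63 ± 0.16 (adjusted p 1.04e-21, and adjusted p = 0.344 with an estimated correlation). Of 11 astrocyte markers 9 rose and 2 fell, including Aldoc (5.94 ± 0.10) and Sparcl1 (10.30 ± 0.22), with an adjusted p of 3.53e-07 and adjusted p = 0.392 with an estimated correlation. Of 16 FGF and ERK feedback genes 15 rose and 1 fell, and the 3 with the smallest p were the receptor Egfr (6.39 ± 0.13), Spred1 (3.20 ± 0.09) and Etv1 (3.34 ± 0.12), with an adjusted p of 2.42e-06 and adjusted p = 0.392 with an estimated correlation. Counts adjusted over the list alone were the same for these 6 lists, as were medians with genes at their bounds. The names of the mESC columns include LIF, and any difference in culture medium between mESC and mNPC is inseparable from cell type. Its part in the changes of the LIF and STAT3 list and of the FGF and ERK list was not tested.

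Cell division, heat shock, p53 and ribosomal genes were lower in mNPC. Of 40 replication genes 34 fell and 4 rose, with Msh2 at -2.78 ± 0.11, Cdt1 at -2.66 ± 0.12 and Mcm3 at -2.01 ± 0.10 (adjusted p 2.42e-06, and adjusted p = 0.702 with an estimated correlation). Of 16 heat shock genes 14 fell and 2 rose, with Hspb1 at -9.72 ± 0.23, Hsp90aa1 at -3.75 ± 0.11 and Hspe1 at -2.93 ± 0.10 (adjusted p 0.000284, and adjusted p = 0.367 with an estimated correlation). Of 22 p53 targets 17 fell and 3 rose, with Phlda3 at -3.44 ± 0.13, Ccng1 at -2.79 ± 0.11 and Tigar at -2.43 ± 0.12 (adjusted p 0.000483, and adjusted p = 0.496 with an estimated correlation). Of 70 cytosolic ribosomal protein genes 49 fell and 12 rose, with Rps17 at -2.44 ± 0.10, Rplp2 at -2.38 ± 0.10 and Rpl29 at -2.57 ± 0.11 (adjusted p 0.00312, and adjusted p = 0.899 with an estimated correlation). Ribosomal protein genes have many processed copies, so the level of Rpl29 and its relatives is uncertain. Counts adjusted over the list alone were the same for these 4 lists.

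The 6 named genes with the highest log2 fold change included 5 without a count in mESC: the glycoproteins Gpm6b (chromosome X, 166238911 to 166388988; at least 14600-fold higher in mNPC) and Gpm6a (at least 3650-fold), the brain fatty acid binding protein Fabp7 (at least 13800-fold), the protocadherin Pcdh9 (at least 1990-fold) and ceruloplasmin (Cp, at least 1420-fold). The sixth, pleiotrophin (Ptn), went from 0.143 ± 0.136 to 1265 ± 65.8 CPM. Cp was at 100 ± 71.3 CPM in mNPC with an adjusted p of 0.0311 by edgeR's quasi-likelihood test, and was lost without mESC replicate 1 (0.0585) and without a low-count filter (0.109). The 6 lowest were Tfcp2l1 and 5 genes with 1 count over both mNPC libraries: Tdh, which breaks down threonine (17400-fold lower, interval 3120 to 686000), the imprinted RNA Meg3 (6250-fold, 1120 to 247000), Zscan10 (5290-fold, 948 to 209000), the desmoglein Dsg2 (4870-fold, 873 to 192000) and the connexin Gjb3 (4240-fold, 761 to 168000).

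Another 6 lists passed in the mouse comparison: mitochondrial ribosomal proteins (16 higher and 43 lower of 74), proteasome subunits (4 and 21 of 31), cholesterol synthesis (16 and 3 of 21), G2/M and mitosis (4 and 24 of 35), oligodendrocyte lineage markers (5 and 1 of 7) and the Notch pathway (13 and 3 of 16), with adjusted p = 0.367 to 0.796 with an estimated correlation. The other lists did not pass. Their counts, higher then lower, were 31 and 25 of 75 oxidative phosphorylation genes, whose median of 0.02 was -0.01 with RLE scaling, 0 and 3 of 6 mitochondrially encoded, 9 and 8 of 17 glycolysis, 11 and 9 of 25 ATF4, 7 and 9 of 19 unfolded protein response, 6 and 9 of 16 interferon, 1 and 3 of 6 NF-kB, 6 and 9 of 17 NRF2, 7 and 9 of 18 hypoxia and 8 and 7 of 18 immediate early genes. They were 16 and 8 of 26 matrix, 8 and 4 of 13 YAP/TEAD, 4 and 0 of 7 fibroblast, 0 and 2 of 3 blood and endothelial, 4 and 6 of 10 primed, 5 and 7 of 13 neuron, 3 and 3 of 7 mesoderm, 7 and 1 of 8 endoderm, 2 and 3 of 5 trophectoderm and 1 and 4 of 5 germline genes. They were 13 and 3 of 16 Hox, 8 and 5 of 14 Wnt, 4 and 7 of 12 DNA methylation and 7 and 6 of 14 imprinted genes and 49 and 39 of 98 transcription factors with reporters, and 0 of the 2-cell-like markers were tested. Adjusted over the list alone, counts differed for oxidative phosphorylation (23 lower), mitochondrially encoded (2 lower), NRF2 (7 higher) and immediate early genes (8 lower). Median, mean and test differed in sign for oxidative phosphorylation, glycolysis, ATF4, unfolded protein response, immediate early, neuron, mesoderm, imprinted and transcription factor genes.

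**Figure D3:**
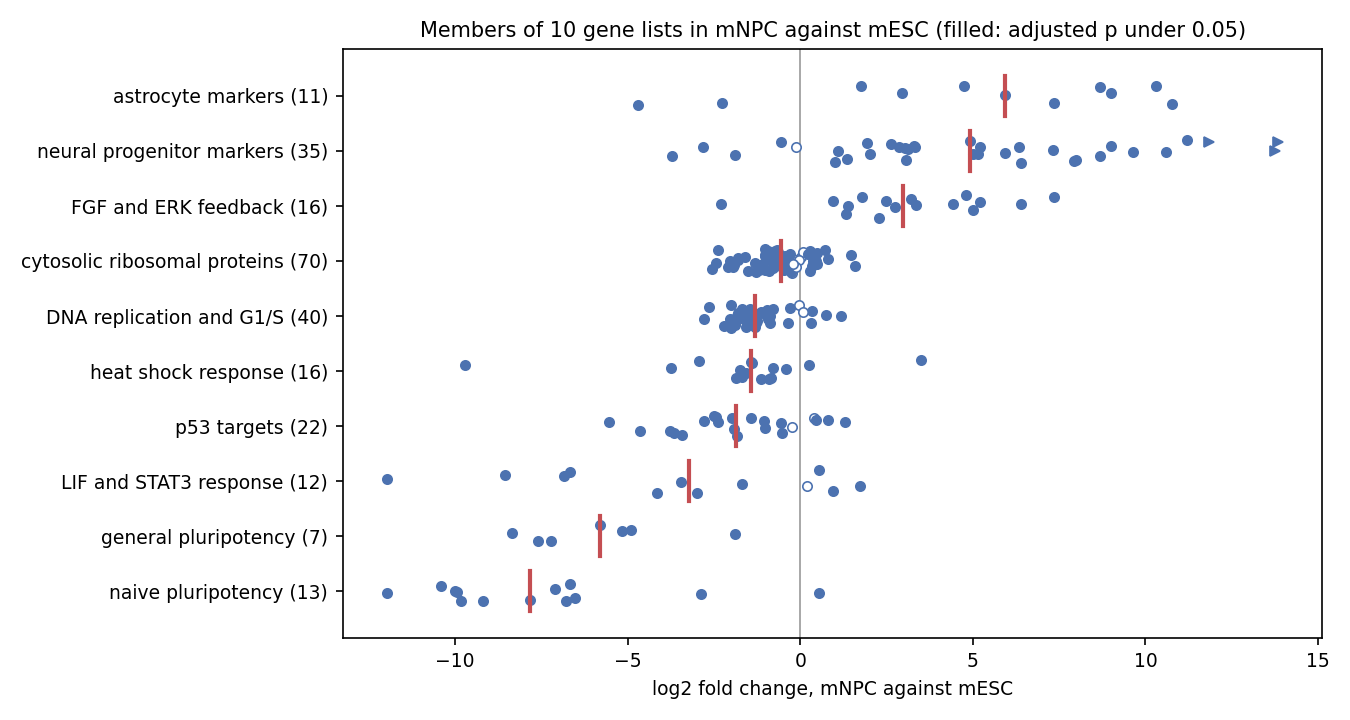
Log2 fold change of each member of 10 gene lists in mNPC against mESC, with genes without a count in a group at their bound. All 7 general pluripotency genes lie below 0, and 30 of 35 neural progenitor markers were called higher.

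Transcription factors for which reporters exist were counted as detected where every library of a cell type had at least 1 CPM over its table's total, without a test. Of 118 factors 91 were detected in HepG2, 82 in mESC and 92 in mNPC, and 68 in all 3. HepG2 was alone in 10, FOSL1, HNF1B, HNF4A, NR1H3, NR1H4, NR1I2, ONECUT1, PPARG, TP53 and VDR. Symbols were matched between species by letters alone, so the mouse genes for TP53 and TP63, which carry other symbols, were not looked up. The counts detected in mESC, in mNPC and in all 3 may thus be too low, and the count detected in none too high. TP53 stands among the 10 without its mouse level being known. It counts in the same way at the other levels below. Stem cells were alone in 7, GLI1, GRHL2, MAFA, NANOG, SPI1, TFAP2C and TFCP2L1, and mNPC in 8, AR, ETS1, LEF1, MEF2C, NFATC1, NR4A2, POU3F2 and RUNX2. These sets depend on the level required. At 0.5 CPM 91, 92 and 94 factors were detected in HepG2, mESC and mNPC, and 7, 5 and 3 were found in 1 cell type alone, the 3 of mNPC being MEF2C, NFATC1 and RUNX2. At 5 CPM 82, 70 and 76 were detected and 13, 8 and 9 were found in 1 cell type alone, of which 8, 5 and 5 were so at 1 CPM. HepG2 and mNPC shared 11 not detected in mESC, mESC and mNPC 5, and HepG2 and mESC 2, HNF1A and POU5F1; 7 were detected in none. The highest in HepG2 were XBP1 (512 ± 22.9 CPM), ATF4 (434 ± 39.7) and HNF4A (341 ± 27.6), in mESC Pou5f1 (1315 ± 106), Tfcp2l1 (843 ± 93.7) and Esrrb (747 ± 67.5), and in mNPC Srebf2 (774 ± 55.6), Zeb1 (510 ± 77.3) and Nfe2l1 (479 ± 38.6). The knocked down factors HNF1A, MTF1 and NRF1 were at 80.1 ± 3.97, 26.7 ± 4.42 and 13 ± 2.71 CPM in HepG2 by this measure. A factor not matched in a table counted as not detected there. This applied to GATA1 and SPI1 in HepG2, to TP53 and TP63 in mESC by their symbols, and to 13 entries in mNPC, TP53 and TP63 among them.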

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

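The replicate block by the HepG2 column endings and the fit over genes of either mouse list were chosen after the data were seen; the other settings, the mouse block included, were planned. Of the named gene values, 1064 kept direction and side of the threshold under the scalings, filters, DESeq2, block and 2-group fits, 46 passed only there and 4 were lost. With 1 library left out 1056 stayed, 107 were lost and 22 gained, and where this left 1 library in a group that library was assumed to vary like the other groups. A value lost with 1 library left out kept its direction and moved above the threshold, which does not show that the change is absent. TFB2M in the NRF1 knockdown, for example, was at -1.10 without NRF1 knockdown replicate 1 and at -0.82 without replicate 2. With the other 2 knockdowns as controls 77 stayed, 24 were lost and 3 gained. Under that setting TOP2A (0.13, adjusted p 0.808 by edgeR's quasi-likelihood test) and MAD2L1 (0.11, 0.841) changed sign in the HNF1A knockdown without passing. In the NRF1 knockdown RFC5 (0.055, 0.904), MAD2L1 (0.039, 0.955) and TOP2A (0.71, 0.151) did the same, whereas HNF1A (1.01, 0.0345) passed with its sign changed. The contrast sets 1 knockdown against 2 others in which these genes also fell, HNF1A by its own knockdown. It called 887 genes for MTF1 and 692 for NRF1. With a change of at least 2-fold as well, which can only remove calls, counts were 946, 1062 and 255 for HNF1A, MTF1 and NRF1 against HepG2 and 733, 504 and 349 against the other 2 knockdowns, and shared calls 315, 60 and 87. At an adjusted p under 0.01 shared calls were 138, 12 and 24. With the replicate block counts were 3802, 3936 and 1777 against HepG2 and 3354, 2736 and 2457 against the other 2 knockdowns, shared calls 1580, 761 and 985, and 17 lists passed for NRF1 against the other 2 knockdowns; the block ended no call of a named gene or described list. Fits of the 2 groups alone called 1004 genes for HNF1A and 778 for NRF1. Without a low-count filter 991 genes were called for NRF1, and 1578 and 1326 for MTF1 and NRF1 against the other 2 knockdowns; DESeq2 called 1110, 1480 and 1379. The cause was not tested for the block, the 2-group fits, the filter and DESeq2. With an estimated correlation 0 lists passed in the 4 main comparisons and in NRF1 against the other 2 knockdowns, and 2 each for HNF1A and MTF1 there. Leaving out 1 library gave 676 to 2070 genes for HNF1A, 499 to 2522 for MTF1 and 13 to 886 for NRF1 against HepG2, 731 to 1304, 193 to 1242 and 82 to 1233 against the other 2 knockdowns, and 10786 to 11387 in mouse. Lists passing ranged from 14 to 20, 17 to 21 and 11 to 14 against HepG2, 16 to 24, 15 to 19 and 10 to 16 against the other 2 knockdowns, and 14 to 17 in mouse. Thinned to 10894238 counts per library, 1682, 1840 and 409 genes were called for HNF1A, MTF1 and NRF1. The mouse replicate numbers do not pair the libraries (correlation 0.00682), and with them as a replicate block 11559 genes were called. With genes listed for either cell type 12675 were called.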

Other observations

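All tests below except the one on depth were chosen only after the result was seen, as were the genes named here. How the tests on a further fall of mitosis genes and on slower cell division are read was changed after their values were seen. Some stem cell and glial genes are listed in only 1 of the mouse tables. Pou5f1, the factor that holds cells pluripotent, was at 1414 ± 119 CPM in mESC and at least 13000-fold lower in mNPC, and Zfp42 (756 ± 33.5 CPM, at least 6950-fold), Tdgf1 (615 ± 115, at least 5650-fold), Sall4 (330 ± 8.53, at least 3040-fold) and Fgf4 (244 ± 25.3, at least 2240-fold) were also listed for mESC alone. The neuron marker Stmn2 (192 ± 42.6 CPM) was also listed for mESC alone. Listed for mNPC alone were the oligodendrocyte and progenitor factor Olig2 (397 ± 12.2 CPM), the astrocyte genes Mlc1 (544 ± 12.2) and S100b (89.5 ± 20.4), and the mitochondrially encoded mt-Co2 (9.56 ± 0.563), mt-Co3 and mt-Atp6, which all cells use. Of the lists, 13 naive and 10 general pluripotency genes, 9 germline genes and 8 2-cell-like markers were listed for mESC alone. The bounds take a gene missing for mNPC as one without counts, which was not tested; the mNPC table lists 0 genes without a count. The mESC table lists 2280, so a gene missing there is not taken as 0 here and no fold change is given.

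The medians of cell division genes were lower in all 3 knockdowns than in HepG2. In the NRF1 knockdown most mitosis genes were not called. Neither the replication nor the mitosis list passed with an estimated correlation in any of the 3. A difference between the r1 and r2 libraries is argued against, since the median over both lists was -0.917 or lower in each of the 6 contrasts within r1 or within r2. These contrasts are not independent. Each sets 1 knockdown library against the mean of NT1_r1 and NT2_r1, or against NT1_r2 alone. With every library thinned to the same depth the median nearest to 0 was -0.981. For the part that all 3 share, with a median of -0.999 or lower, a state of the HepG2 libraries or of all knockdown cultures cannot be told apart from an effect of each factor, as there are no other control libraries. The mitosis median in the MTF1 knockdown against the other 2 knockdowns was -1.05, -1.46 within r1 and -0.52 within r2, with adjusted p = 0.332 with an estimated correlation. Against HepG2 the mitosis median was -2.49 within r1 and -2.07 within r2 in the MTF1 knockdown, and -0.96 and -0.93 in the NRF1 knockdown. In the HNF1A knockdown it was -0.99 and -2.14. A state that all 3 knockdowns share alike drops out of such differences by definition, so they do not test it. The difference between the MTF1 and NRF1 medians is not one that such a state could give. These 2 knockdowns were not tested against each other. Within r2 the MTF1 median was no lower than the HNF1A median, so a fall beyond that of the HNF1A knockdown is not decided.

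Of 33 interferon response genes 18 were higher in the MTF1 knockdown, and the list had adjusted p = 0.276 with an estimated correlation (0.125 against the other 2 knockdowns). The r1 and r2 difference moves these genes, yet the median was 1.31 or higher within each ending, and against the other 2 knockdowns 1.63 or higher within each, which argues against a response to any knockdown. Lower MTF1 may raise these genes, but the 18 genes called higher cannot be told apart from another property of the MTF1 knockdown cultures, as the labels name 1 MTF1 knockdown group and do not say how many separate knockdowns it holds.

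Of 31 proteasome subunit genes 11 were lower in the MTF1 knockdown, and the list had adjusted p = 0.531 with an estimated correlation. PSMD11 and PSMD12 did not pass against the other 2 knockdowns (0.165 and 0.341), whereas PSMD1 kept its call there. NFE2L1, known to activate these genes, also fell in the MTF1 knockdown, a call lost without its replicate 1 or 2 (adjusted p 0.0934 and 0.0574). Slower cell division may contribute. In the HNF1A knockdown, where most cell division genes also fell, no proteasome gene was called. The proteasome median there was -0.0052 (0.0069 with RLE scaling), -0.12 within r1 and 0.14 within r2. In the MTF1 knockdown it was lower within each ending, at -0.31 within r1 and -0.52 within r2. In the NRF1 knockdown, where the cell division medians were also lower, it was -0.20 and -0.31, so the other 2 knockdowns differ and do not decide this. Lower NFE2L1 may contribute, but the median was also -0.258 in the NRF1 knockdown, where NFE2L1 did not pass the test, and that list had adjusted p = 0.868 with an estimated correlation, so both explanations stay open.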
